A study of Caenorhabditis elegans with 4 samples.

How the data were processed

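Chromatin was prepared from C. elegans embryos of strain OP169, a mixed population of males and hermaphrodites grown at 20 degrees Celsius and crosslinked with 2% formaldehyde, per the labels' protocols. Fragments bound by the tagged protein were recovered with anti-GFP antibodies, and 10% of the cleared lysate was kept as input. The series comprised 4 libraries, of which 2 are ChIP and 2 are input. Groups and replicate numbers were taken from the sample titles.

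The authors deposited lists of binding regions with positions on the WormBase WS220 build, per the file headers. The source field of each list names the SPP peak caller and the irreproducible discovery rate, a method that compares the ranks of replicate lists. The score in each list was deposited by the authors without a named unit. It was used only to rank regions within a list, and ties were ordered by the number in the region's name, which followed the score (Spearman's rho -0.968 in the combined list and -0.996 in replicate 2). The aligner, the versions, the thresholds, the use of the input libraries and how the combined list was made are not given in the sources used here. The replicate lists are per sample, and the combined list has no replicate. Replicate 1 holds 30000 regions, a round number, and whether a maximum was set is likewise not given in the sources used here. The length of each list depends on such settings as well as on the signal. No read counts were used, so the depth of the libraries is unknown.

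Regions were compared with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15 and plotted with matplotlib 3.10.9. Regions on mitochondrial DNA were left out of the nuclear comparisons. Regions that overlapped by at least 1 bp counted as shared. Chance overlap was estimated from 1000 circular shifts of the other list within each chromosome, by at least 10000 bp, and from 100 shifts for the breakdown by rank. The length of each chromosome was taken as the largest region end in any list (15053012 bp for I, 15274280 for II, 13779905 for III, 17489881 for IV, 20918708 for V and 17718022 for X), which can only understate it. X and autosomal counts were compared with an exact binomial test given these lengths. Intervals over 1-Mb bins came from 10000 bootstrap resamples, and permutation tests over bins or region pairs used 100000 resamples unless another number is given. To measure what chance overlap does to a split into shared and unshared regions, the other list was moved 200 times by 5000 to 50000 bp, which keeps its density profile. Partial bins at chromosome ends were left out, and neighbouring bins are not fully independent. Binomial, Poisson and Wilson intervals cover counting error only.

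The overlap and density calculations were tested on simulated data with the list lengths of replicates 1 and 2. For replicate 2 against replicate 1, a shared part of 40% was recovered as 39.8%, an X ratio of 1.5 as 1.51, and an unrelated list gave an overlap of 22.8% against 22.6% after shifting. Simulated regions were placed evenly at random within each chromosome. The simulation therefore does not test how the uneven density of the real lists affects circular shifts.

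The replicate overlap, the score correlation, the support of the combined list, the binomial comparison of X with the autosomes and most of their alternatives were fixed before the data were examined. The alternatives were stricter overlap rules, the best-scoring part of each list, single replicates and the central part of each chromosome. Added after the data were seen were the breakdowns by rank, the comparisons of the combined list with equally long replicate lists, the tests over 1-Mb bins, the spread among chromosomes, the omission of chromosome V, joined loci, the pairs outside the combined list, the central and outer chromosome parts, the mitochondrial regions, the shifts of the combined list, the short shifts and the spacing of loci. The 5 comparisons set out beforehand that need genes or sequence (promoter share, bound genes on X and autosomes, gene lists, motif enrichment and motif by rank) were not run. No genome of the WS220 build was used, and the gene table used here names another assembly, so its positions were not mixed with those of the regions. For the same reason the rule for named genes was applied to regions, and the 15 combined regions with the highest score are named or counted by position. The 5 highest regions on X were added after the data were seen.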

Results

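CEH-39 is a homeodomain protein of the ONECUT class, encoded on the X chromosome of Caenorhabditis elegans and known as one of the X signal elements through which the embryo counts its X chromosomes. Its binding was mapped in embryos by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The animals carried a transgene that expresses CEH-39 fused to EGFP and FLAG tags, so that anti-GFP antibodies could recover the factor with its crosslinked DNA. The design comprised 2 ChIP libraries and 2 input libraries of total DNA. Binding regions were analysed for the 2 ChIP replicates and for 1 combined list, and the input libraries were not analysed here. The labels do not say whether the replicates came from separate cultures, so differences between them measure the spread between these libraries, which may be technical.

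The replicate 1 list held 30000 regions and the replicate 2 list 19048, whereas the combined list held 2515. Most regions of a list had one width, which was 460 bp for 98.7% of the replicate 1 regions, 416 bp for 19039 of the replicate 2 regions and 464 bp for 90.5% of the combined regions. Joining overlapping regions left 24989 loci in replicate 1, 17502 in replicate 2 and 2443 in the combined list, and these loci covered 12.7, 7.65 and 1.09 Mb. The score of each region is the authors' own, on a separate scale in each list, and many regions tied at the highest value. The ties comprised 991 combined regions (39.4%), 1332 replicate 1 regions (4.44%) and 112 replicate 2 regions (0.588%). Read depth was unknown.

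The highest-ranked combined regions overlapped regions of both replicates. If the combined list was built from these libraries, this follows in part from its making. The top-ranked combined region lay on chromosome II at 11979639 to 11980058 (WS220), and it overlapped the replicate 1 region of rank 4 and the replicate 2 region of rank 3. The next lay on chromosome V at 9344137 to 9344588, at ranks 11 and 1 in replicates 1 and 2. Chromosome I carried the third, at 6799516 to 6799829 (ranks 2 and 20), the fourth, at 8059445 to 8059793 (ranks 3 and 45), and the sixth, at 9988781 to 9989150 (ranks 24 and 2). On chromosome III the highest lay at 10758955 to 10759258 (ranks 9 and 17). Another chromosome III region, at 5958142 to 5958443, ranked 1 in replicate 1 and 161 in replicate 2. Chromosome IV carried regions at 4749933 to 4750192 (ranks 20 and 4) and at 8432804 to 8433115 (ranks 5 and 60).

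Each of the 15 highest combined regions overlapped regions of both replicates. All 15 were within the best 24 ranks of replicate 1, and 14 were within the best 100 of replicate 2. They were 165 to 452 bp wide, and 3 were on chromosome I, 4 on II, 3 on III, 2 on IV, 2 on V and 1 on X. The highest X-linked region, at 1856291 to 1856455, had combined rank 14 and ranks 8 and 64 in replicates 1 and 2. The next on X lay at 15606855 to 15607120 (combined rank 17), 2996986 to 2997198 (rank 20), 14297083 to 14297350 (rank 26) and 7823116 to 7823371 (rank 27). The region of combined rank 26 ranked 12 in replicate 1 and 730 in replicate 2. All these regions shared the highest combined score, so their order rests on the number in each region's name. Whether they lie in promoters, exons or introns, and of which genes, was not analysed here, because no annotation of the WS220 build was used.

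The first comparison was between the replicates. Of the replicate 2 regions, 9646 (50.6%, 95% Wilson interval 49.9 to 51.4%) overlapped a replicate 1 region by at least 1 bp, and 10620 of the 29978 nuclear replicate 1 regions (35.4%, 34.9 to 36.0%) overlapped a replicate 2 region. When the other list was shifted circularly along each chromosome, the mean overlap was 23.0% and 15.7%, and the highest of 1000 shifts gave 24.2% and 16.4%. The observed shares were 2.20 and 2.25 times the shifted means (one-sided permutation test, p = 0.001 for both, the smallest that 1000 shifts can give). Among the best 2515 regions of each replicate, 46.5% of the replicate 2 regions and 46.2% of the replicate 1 regions were shared, against 2.21% and 2.19% after shifting. Circular shifts keep the widths and spacing of regions but not their position relative to genes or the density profile along the chromosome. The short shifts, which keep that profile, gave a chance overlap of 23.8% for replicate 2 regions and 16.4% for replicate 1 regions.

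Overlap fell with rank, a breakdown added after the data were seen. The best 500 ranks of replicate 1 were found in replicate 2 in 95.2% of cases (92.9 to 96.7%), and those of replicate 2 in replicate 1 in 96.4% (94.4 to 97.7%). At ranks 1001 to 2500 the shares were 74.2% and 69.8%, and at ranks 2501 to 5000 they were 56.5% and 56.7%. At ranks 10001 to 19048 they were 29.5% and 42.1%, against 15.7% and 23.0% after shifting. The replicate 1 regions at ranks 19049 to 30000, beyond the length of the replicate 2 list, were shared in 24.6% of cases (23.8 to 25.5%), against 15.8% after shifting.

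**Figure D1:**
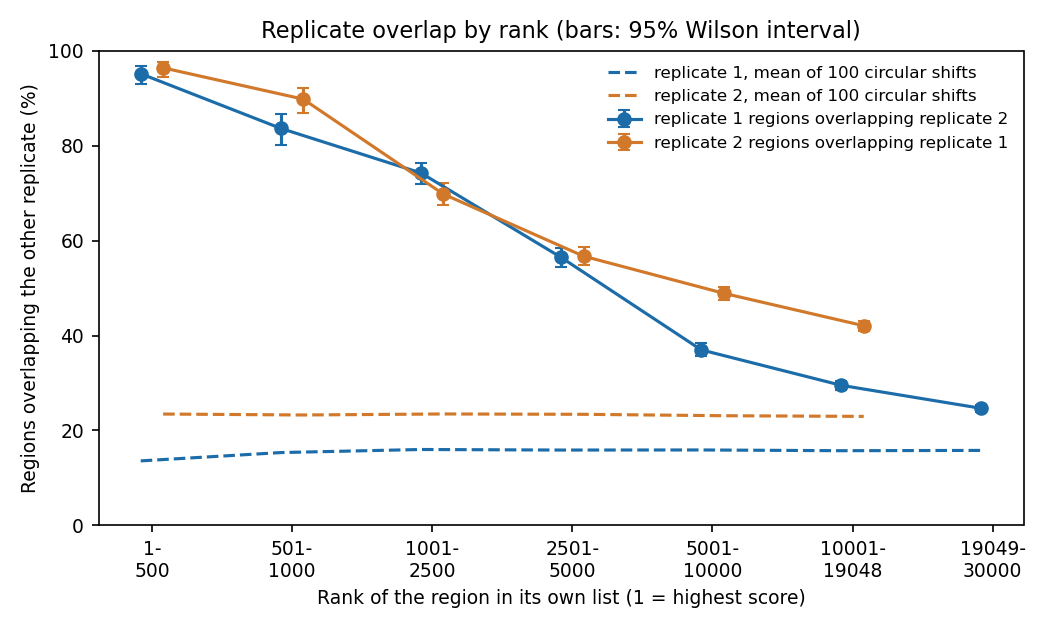
Share of each replicate's nuclear regions that overlap the other replicate's list by at least 1 bp (y axis, percent) by the region's rank in its own list (x axis, classes of rank), where points with 95% Wilson intervals are observed shares and dashed lines the mean of 100 circular shifts. The share falls from 95.2% and 96.4% in the best 500 ranks of replicates 1 and 2 to 29.5% and 42.1% at ranks 10001 to 19048, and lies above the shifted mean in every class.

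Regions shared by the replicates were also ranked in a related order by the authors' scores. Over the 6033 pairs of regions that matched one to one, Spearman's rho was 0.376 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). It was 0.198 over the 1234 pairs that also overlapped a combined region (permutation p = 1e-05). Over the 4799 pairs that overlapped none, a subset added after the data were seen, it was 0.102 (permutation p = 1e-05). These correlations run across regions, which are not independent replicates.

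Most combined regions were found in both replicates, and more were found in replicate 1 than in replicate 2. Of the 2515 combined regions, 2213 (88.0%, 95% Wilson interval 86.7 to 89.2%) overlapped a region of both, against a mean of 7.61% and a highest value of 9.46% over 1000 circular shifts of the combined list. How the combined list was made is not given in the sources used here, and if it was built from these libraries, overlap with both follows in part from its making. Only replicate 1 was overlapped by 287, only replicate 2 by 14 and neither by 1. Overlap with both was 98.6% among the first 503 combined regions by rank and 77.7% among the lowest 503. Because 991 combined regions tied at the highest score, the number in the region's name decided which came first. The replicate 1 list is the longer, so a comparison at equal length was added after the data were seen. Against the best 2515 regions of each replicate, 87.5% of the combined regions overlapped replicate 1 and 53.4% replicate 2. Of the combined regions that overlapped only one of these shorter lists, 1052 overlapped replicate 1 and 196 replicate 2 (exact McNemar test, two-sided, p = 6.76e-142, which takes regions as independent).

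The next comparison, implied by the X-linked target, set X against the autosomes. The combined list held 24.0 regions per Mb on X (425 regions) and 25.3 per Mb on the autosomes (2090 regions), a ratio of 0.947 (95% exact interval 0.851 to 1.05) that did not pass the exact binomial test (two-sided, p = 0.321). As whole lists, the replicates lay on opposite sides of equality. In replicate 1 the ratio was 0.832 (0.806 to 0.859), with 256 regions per Mb on X and 308 on the autosomes (exact binomial p = 2.31e-31, Benjamini-Hochberg adjusted over the 3 lists 6.92e-31). In replicate 2 it was 1.06 (1.02 to 1.096), with 199 and 188 regions per Mb (exact binomial p = 0.00324, adjusted 0.00486). The best 500 ranks did not show this opposition, in a breakdown added after the data were seen. There the ratio was 1.15 (0.910 to 1.43) in replicate 1 and 1.14 (0.901 to 1.42) in replicate 2. At ranks 10001 to 19048 it was 0.835 (0.787 to 0.884) and 1.04 (0.986 to 1.098).

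The binomial test takes regions as independent, so the comparison was repeated with 1-Mb bins as the unit, a test added after the data were seen. The combined list gave 24.1 ± 4.76 regions per bin on X (SD, n = 17 bins) and 25.4 ± 10.9 on the autosomes (SD, n = 80 bins), with a two-sided permutation p of 0.643. Replicate 1 gave 254 ± 55.9 on X and 304 ± 98.7 on the autosomes (permutation p = 0.0481, adjusted over the 3 lists 0.144). Replicate 2 gave 199 ± 22.5 and 188 ± 42.1 (permutation p = 0.298, adjusted 0.447). The X-to-autosome ratio of replicate 2 was 1.27 times that of replicate 1 (95% bootstrap interval 1.13 to 1.41, with the same bins drawn in both lists). This interval covers variation along the genome, not variation between libraries.

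Chromosomes I and III were the densest and chromosome V the sparsest in all 3 lists. The combined list held 35.2 regions per Mb on I (95% exact Poisson interval 32.3 to 38.3), 34.5 on III (31.4 to 37.7), 26.2 on II (23.7 to 28.9), 24.0 on X (21.8 to 26.4), 21.9 on IV (19.8 to 24.2) and 14.4 on V (12.9 to 16.2). The densest chromosome exceeded the sparsest 2.44-fold in the combined list, 1.79-fold in replicate 1 and 1.53-fold in replicate 2. In each list the spread among the 6 chromosomes exceeded that of 10000 permutations of the 1-Mb bins (permutation p = 0.0001, the smallest they can give), a test added after the data were seen. With V left out, also chosen afterwards, the X-to-autosome ratio of the combined list was 0.826 (0.742 to 0.919, exact binomial p = 0.000351), and over 1-Mb bins it was 0.831 (95% bootstrap interval 0.735 to 0.943, permutation p = 0.0494). Leaving out the sparsest autosome lowers this ratio by construction, so these p-values are no evidence of fewer regions on X.

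**Figure D2:**
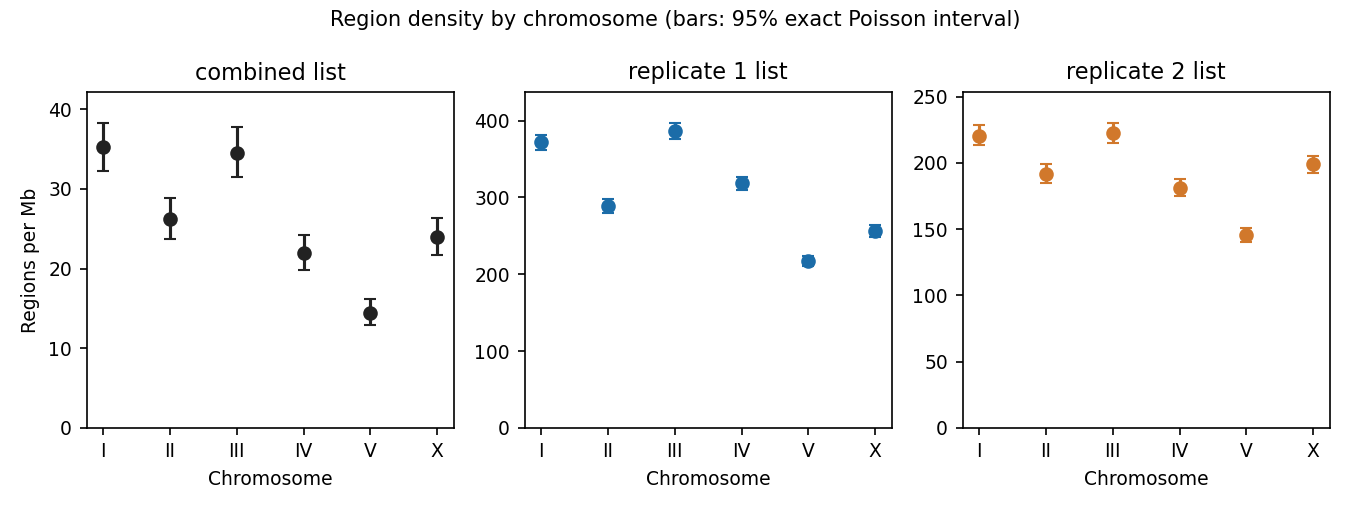
Regions per Mb (y axis, from 0, with a separate scale per panel) on each nuclear chromosome (x axis) in the combined, replicate 1 and replicate 2 lists, with 95% exact Poisson intervals. Chromosomes I and III are highest and V lowest in each panel, and X stands at 24.0, 256 and 199 regions per Mb.

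Along the chromosomes the replicates had different profiles, a comparison added after the data were seen. In replicate 1, 39.8 to 45.3% of the regions of each autosome lay in its central 50%, against 52.2 to 56.3% in replicate 2. In the combined list the central share was 53.2 to 60.9% on the autosomes and 45.6% on X. The ratio of central to outer density on the autosomes was 1.67 times as high in replicate 2 as in replicate 1 (95% bootstrap interval over bins 1.54 to 1.82). In replicate 1 the central share of autosomal regions was 54.02% in the best 500 ranks and 39.0% at ranks 10001 to 19048, and in replicate 2 it was 59.95% and 51.8%.

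**Figure D3:**
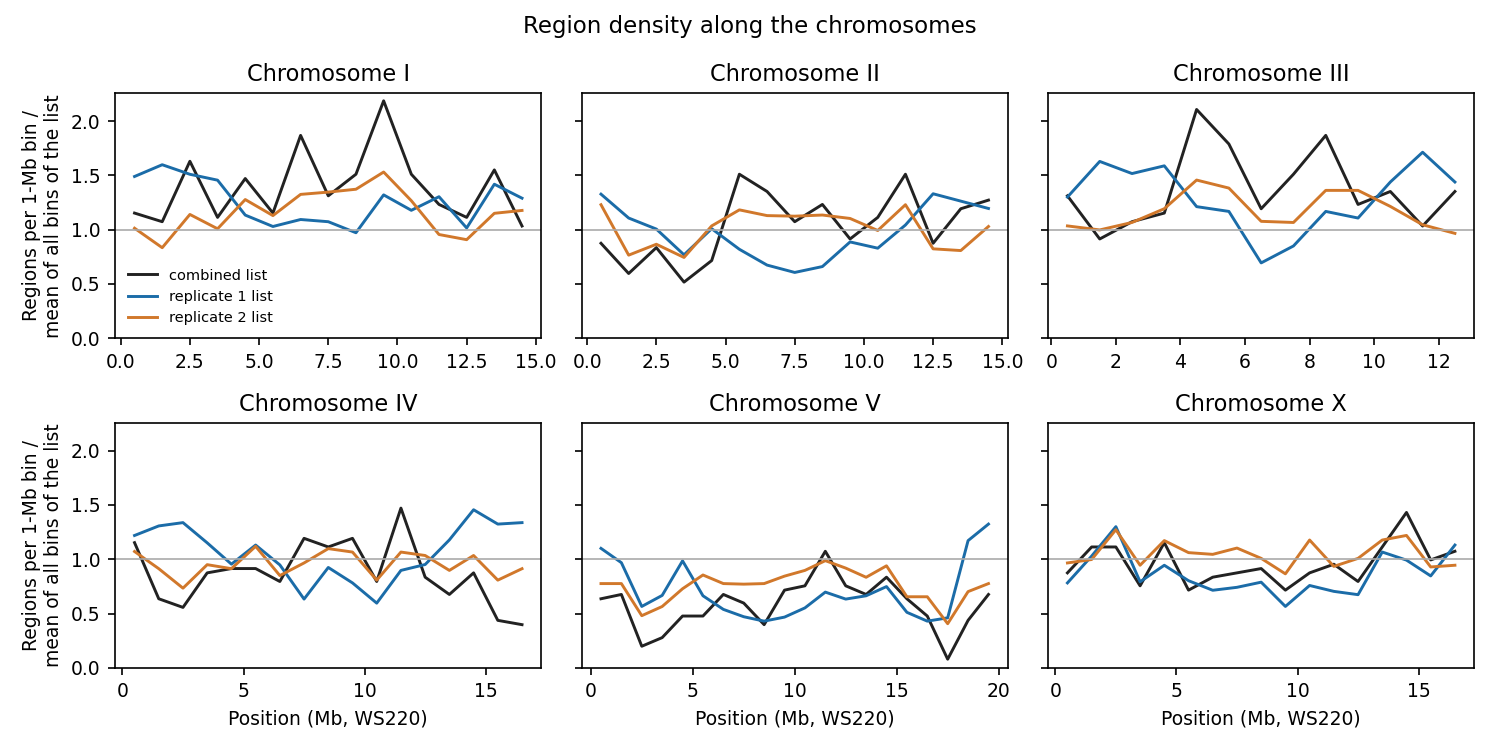
Regions per 1-Mb bin divided by the mean of all bins of the same list (y axis) along each nuclear chromosome (x axis, Mb on WS220) for the combined list and both replicate lists, with a grey line at the list mean. On chromosomes II to V the replicate 1 line is lower in the middle than towards the ends, and 39.8 to 40.6% of its regions on each lie in the central 50%, against 52.2 to 55.5% for replicate 2.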

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

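The tests in this part were chosen after the result was seen.

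Replicate 1 held 22 regions on mitochondrial DNA, outside the nuclear comparisons, while replicate 2 held 0 and the combined list 0. They draw attention because 22 exceeds the 3 that a count of 0 allows when regions are taken as independent. Regions this close together need not be independent, so that limit is a guide only. Their ranks ran from 94 to 9436 with a median of 1538. The longer list of replicate 1 is argued against as the source, because 22 of the 22 rank within the length of the replicate 2 list. Mitochondrial DNA carried over as whole molecules is a candidate explanation that their coverage cannot decide. The regions covered 61.1% of the mitochondrial span, against 12.6% of the nuclear span for the nuclear regions of the same list. Each of 10 equal parts of the span held 2 to 3 of them. Coverage follows largely from their number, because 22 regions near the list's usual 460 bp would cover much of 13288 bp wherever they fell. This span was taken as the largest end of these same regions. No biological explanation was tested, and the input libraries were not analysed here.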

How the results depend on the processing

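The alternatives with equally long lists (except for the replicate overlap), without chromosome V, with joined loci, over 1-Mb bins and with pairs outside the combined list were chosen after seeing the data. The replicate overlap stayed above all circular shifts under each alternative (37.01 to 46.5% of replicate 2 regions, 24.5 to 46.2% of replicate 1 regions), and the score correlation stayed positive (0.102 to 0.406, each with permutation p = 1e-05, the smallest possible). Overlap of the combined list with both replicates was 83.2% when 50% of the shorter region had to overlap, 77.8% with the best-scoring 50% of each replicate list and 45.6% with the best 2515 regions of each, and the last 2 settings shorten the replicate lists by construction. The X-to-autosome ratio did not keep one direction. In the replicate 1 list alone it was 0.832 and in the replicate 2 list alone 1.06, and the combined list was not remade without a replicate. The ratio was 1.004 in the best-scoring 50% of the combined list (exact binomial p = 0.941) and 1.04 in the best 2515 regions of replicate 2 (exact binomial p = 0.418). It was lower and passed the exact binomial test at 0.899 over replicate 1 regions that overlap replicate 2, 0.758 in the central 50% of each chromosome and 0.826 without chromosome V, the sparsest autosome. Over 1-Mb bins the first 2 did not pass (0.899, permutation p = 0.225, and 0.766, permutation p = 0.0786), and the last was 0.831 (permutation p = 0.0494). Without V the ratio falls by construction, because V is the sparsest autosome. Joined loci (0.942), the best 2515 regions of replicate 1 (0.920) and the whole combined list over 1-Mb bins stayed below 1 and did not pass. The cause of the other changes was not tested. No paired analysis was possible because the input libraries have no region list analysed here, so no test compares the 2 groups. Leaving out a replicate gives no overlap, score correlation or joint support. The alternatives for promoter share, bound genes, gene lists and motifs were not run. Ties limit the ranking of the best 991 combined, 1332 replicate 1 and 112 replicate 2 regions, and read depth is unknown.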

Other observations

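The comparisons in this part were chosen after the data were seen, and so were the tests of list length and of replicate 1 as the whole cause. The tests of shared against unshared regions within replicate 1 and of neighbours 1000 to 2000 bp apart were set before their own results were seen, but after other properties of the same lists had been examined. The explanation by background in replicate 1 was first set out as the only cause, and that wording was dropped after its result was seen. The checks of whether those splits can decide anything were also added afterwards.

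Combined regions were denser in the central 50% of the autosomes and sparser in that of X. On the autosomes, central 1-Mb bins held 28.6 ± 10.96 regions (SD, n = 41 bins) and outer bins 22.03 ± 9.81 (SD, n = 39 bins), a ratio of 1.30 (95% bootstrap interval 1.09 to 1.57, two-sided permutation p = 0.00663, Benjamini-Hochberg adjusted over 6 tests 0.00994). On X the central bins held 21.9 ± 3.37 (SD, n = 9 bins) and the outer bins 26.6 ± 5.01 (SD, n = 8 bins), a ratio of 0.822 (0.707 to 0.966, permutation p = 0.0333, adjusted 0.0400). In the best-scoring 50% of the combined list the ratio was 1.29 on the autosomes (1.06 to 1.59, permutation p = 0.0165) and 0.833 on X (0.661 to 1.07, permutation p = 0.202), so the X difference did not pass there. On the autosomes the ratio was 1.19 (1.09 to 1.30) in replicate 2 but 0.712 (0.631 to 0.803) in replicate 1. Among the best 2515 regions it was 1.43 (1.20 to 1.72) in replicate 2 and 1.18 (0.991 to 1.41) in replicate 1, so the direction in replicate 1 turned with list length. On X it was 0.749 (0.648 to 0.871) in replicate 1 and 0.986 (0.888 to 1.09) in replicate 2.

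As a whole list, replicate 1 thus had a lower share of X and of central regions than replicate 2. Its longer list is argued against as the whole source, because at the length of replicate 2 the ratio of replicate 2 was still 1.30 times that of replicate 1 for X (95% bootstrap interval 1.17 to 1.43) and 1.60 times for the central share (1.48 to 1.73), although among the best 2515 regions of each these fell to 1.13 (1.01 to 1.27) and 1.21 (1.11 to 1.32). Background called in replicate 1, and regions of replicate 1 as the whole cause, stay open. The quotient of shared over unshared regions lay within the range of the short shifts for X in replicate 1 (1.12, chance 0.913 to 1.18). In replicate 2 it lay within that range for X (0.7504, chance 0.699 to 0.886) and for the central share (0.663, chance 0.594 to 0.671). The central quotient of replicate 1 lay above its range (1.54, chance 1.12 to 1.28). These ranges cannot decide the cause, because the short shifts left fewer regions shared (16.4% and 23.8% of replicates 1 and 2) than observed (35.4% and 50.6%). The central ratio of the shared replicate 1 regions, 0.938, lay between the whole lists (0.712 and 1.19). That position does not tell which replicate caused the difference. No biological explanation was tested, since the labels give both replicates the same stage, strain and sex.

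Combined loci had more neighbours within 2000 to 10000 bp than at random, but not within 1000 bp (42 against 69.7), where joining overlapping regions removes close pairs. Of neighbouring loci, 425 had centres within 5000 bp, against 328 ± 14.8 (SD over 1000 draws) when each locus was placed at random within its own 100-kb window (one-sided permutation p = 0.001, the smallest the draws can give). One site called as 2 regions was tested with neighbours 1000 to 2000 bp apart, where the excess was 2.04-fold (139 against 68.1). That is farther than the widest combined region of 471 bp, which argues against a site no wider than a region as the whole source. A broader bound stretch called as 2 regions stays open. The widths cannot decide this, because 90.5% of combined regions had one width, 464 bp, which need not be the extent of binding. A hypothesis left untested is that several sites gather at the same regulatory regions, for which gene positions on WS220 would be needed. The fullest 50-kb windows, on chromosome III at 4250001 to 4300000 and at 7150001 to 7200000, held 8 loci each, which random placement along whole chromosomes also reached (permutation p = 0.224).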
